A study of Homo sapiens with 9 samples.

How the data were processed

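HK-2 is an immortalised human kidney cell line derived from proximal tubule epithelium. Per the labels, HK-2 cells were plated for stimulation with transforming growth factor β1 (TGFβ1) for 0, 24 or 48 h, the experiment was run on 3 separate days with consecutive passages, and the plates of each time point were pooled on each day. Each of the 9 arrays therefore holds pooled RNA of 1 time point from 1 run, 3 arrays per group, and the spread between replicates is a spread between runs rather than between plates. The design text names the control group as vehicle while the sample labels name it untreated at 0 h; it is called untreated here. No untreated culture at 24 h or 48 h was analysed here, so the effect of TGFβ1 and the effect of time in culture are confounded. The dose of TGFβ1 is not given in the sources used here.

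RNA was hybridised to a 1-colour Affymetrix expression array. The values deposited by the authors are 1 value per probe set on a log2 scale, made with GCRMA per the submitters' processing notes. GCRMA corrects the background with a model of probe sequence, normalizes between arrays and summarises the probes of a set. Its version is not given in the sources used here. The log base is read from the values themselves, since the highest value of 12.5 lies within the range of a 16-bit scanner on a log2 scale and would lie beyond it on a natural log scale. The deposited log2 values were used with no further normalization. Array medians lay between 2.2 and 2.23, and from 28.2% to 29.3% of the probe sets of an array had a log2 value of at least 4. No detection calls were used here, so values near the median of an array cannot be told from background. Folds that start from or end at such values are compressed. The number of arrays limits the precision.

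The table held 22277 probe sets, of which 62 were controls. The platform annotation gave 19070 probe sets 1 gene symbol, 1043 several and 2164 none. Symbols were updated through the gene IDs of a RefSeq gene table, which matched 19058 probe sets, and no coordinates were taken from it. Only probe sets with 1 symbol were named. They covered 11963 genes, of which 4310 had more than 1 probe set, and the probe set with the highest mean over the 9 arrays stood for the gene. Some of these sets, those of JAG1 and FN1 among them, hold probes that can match related sequences. Genes with a log2 value of at least 4 on at least 3 of the 9 arrays were tested, which left 4368 genes, or 36.5%. Of the fixed set of genes described below, 1 is not reported here.

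Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, all 9 arrays in 1 fit with a shared estimate of the spread), with Benjamini-Hochberg adjustment over the 4368 genes and a threshold of 0.05. The comparisons were 24 h against untreated, 48 h against untreated, 48 h against 24 h, and an F test over the 3 groups. Every adjusted p below comes from this fit unless another test is named. Because the spread is shared, a gene has 1 standard error (SE) for every comparison between groups, and it is printed once. Gene lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data and with fry. The correlation was estimated without the replicate number in the fit, so shifts between runs enter it. camera compares a list with the other genes, while fry asks whether the genes of a list changed at all. Simulated data with the real means and spreads, 4368 genes and 200 changed genes in each of 20 runs, were used to test the script. For 24 h against untreated, 18.5% of genes with a simulated log2 change of 0.5 were called, 68.8% of those with a change of 1 and 95.6% of those with a change of 2, and 4.96% of the calls were false. The simulated arrays were drawn independently of each other. Real arrays of 1 run correlated, as described below, so these shares may not hold for them.

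The replicate numbers in the titles were checked for pairing. Deviations from the group mean correlated at 0.378 to 0.662 between arrays of 1 number and at −0.526 to 0.185 between arrays of different numbers, and all 9 arrays correlated best with their own number. The numbers were taken to mark the days of the experiment, and the fit with the number as a block is printed beside a result where it changes the call or moves a count by over 1.5 times. Replicates are separate runs of 1 cell line. The p-values of the main fit measure the spread between runs, with the shifts shared by the arrays of a run included. Those of the fit with the block measure the spread of differences within runs. The median SE was 0.191 in the main fit and 0.139 with the block.

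The genes named were fixed by a rule written before the data were examined: the 10 largest increases and the 10 largest decreases past the threshold with no overlap between the groups (5 and 5 for 48 h against 24 h), a fixed set of genes whatever their values, and up to 4 members of each gene list. The 35 gene lists, also written before the data were examined, covered TGF-beta early target genes; TGF-beta ligands, receptors and SMADs; the BMP, Notch and Wnt pathways; EMT transcription factors; mesenchymal markers; epithelial junctions and keratins; structural extracellular matrix; collagen processing; matrix proteases and inhibitors; actin cytoskeleton and contractility; integrins; proximal tubule function; cell cycle; CDK inhibitors and cytostatic targets; fatty acid oxidation; oxidative phosphorylation; cholesterol synthesis; glycolysis and hypoxia; oxidative stress response; unfolded protein response; interferon-stimulated genes; inflammatory cytokines and NF-kB targets; antigen presentation; tubular injury markers; growth factor ligands; IGF-binding proteins; immediate early genes; housekeeping controls; and markers of fibroblasts, endothelial cells, leukocytes, podocytes and the distal nephron. The list of IGF-binding proteins also held the receptor genes IGF1R and IGF2R. The 29 lists with at least 5 members tested entered the set tests. List sizes below count members tested, and the other members on the array lay below the filter. Tested were 7 of 20 mesenchymal markers on the array, 11 of 31 epithelial genes and 6 of 13 EMT transcription factors. So were 24 of 49 structural matrix and 5 of 27 proximal tubule genes. Alternatives covered the replicate block, the filter, a floor, normalization between arrays, the choice of probe set, the variance model, the groups in the fit, the threshold and each array or replicate left out.

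The difference between 3' and 5' control probe sets, a measure of RNA quality, was compared with a 2-sided exact permutation test, in which 3 arrays against 3 cannot give a p below 0.1. For ACTB it was 1.08 ± 0.06 (SD, n = 3) on the log2 scale in untreated cells, 0.94 ± 0.08 at 24 h (exact p = 0.2) and 1.03 ± 0.07 at 48 h (exact p = 0.5). For GAPDH it was 0.25 ± 0.09, 0.20 ± 0.03 (exact p = 0.5) and 0.20 ± 0.09 (exact p = 0.6).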

Results

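Gene expression was measured in HK-2 cells, a human proximal tubule epithelial line, before and after exposure to TGFβ1, a cytokine that drives epithelial to mesenchymal transition and fibrosis in the kidney. The 9 arrays formed 3 groups of 3: untreated cells at 0 h, cells at 24 h of TGFβ1 and cells at 48 h of TGFβ1. The series addresses which transcripts change during TGFβ1-driven transition of these cells. The first 3 principal components held 37.6%, 29.1% and 13.6% of the variance, and arrays correlated at 0.985 to 0.994 within a group and at 0.978 or more between groups. All values are log2 values of 1 probe set per gene, and differences are given as log2 fold changes with their SE, 3 arrays per group.

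After 24 h of TGFβ1, JAG1, a ligand of Notch receptors, rose most among the 4368 genes tested. Its mean went from 5.39 to 9.46, a log2 fold change of 4.07 ± 0.41 (16.8-fold, adjusted p = 0.000643). INHBA, which encodes the subunit of activin A, rose 13.4-fold (3.74 ± 0.33, adjusted p = 0.000411), and SLCO2A1, a prostaglandin transporter, rose 7.83-fold (2.97 ± 0.165, adjusted p = 4.51e-05). The largest decrease was that of GDF15, a stress-induced cytokine of the TGF-beta family, which fell 16.4-fold (−4.04 ± 0.40, adjusted p = 0.000643). SCNN1A, the alpha subunit of the epithelial sodium channel, fell 9.16-fold (−3.20 ± 0.345, adjusted p = 0.000818) and the tetraspanin CD9 fell 7.83-fold (−2.97 ± 0.19, adjusted p = 8.02e-05).

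The other increases among the 10 largest at 24 h were those of TAGLN (2.81), TNS1 (2.72), PMEPA1 (2.69), IL11 (2.68), TP53I3 (2.59), TGFBI (2.58) and LMCD1 (2.53). TAGLN and TNS1 encode actin-binding and focal adhesion proteins, IL11 a cytokine and PMEPA1 an inhibitor of TGF-beta signalling. The other decreases were those of CRYM (−3.35), the potassium channel gene KCNJ16 (−3.08), RBM47 (−2.96), MAL (−2.66), VCAM1 (−2.36), IMPA2 (−2.23) and HLA-DMB (−2.06). All of these had adjusted p-values from 4.51e-05 to 0.0225, and by the rule that named them no treated array overlapped an untreated one.

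Of 16 tested early target genes of TGF-beta, 8 rose and 0 fell at 24 h, among them PMEPA1, TGFBI, LTBP2 (1.13, adjusted p = 0.00118) and LMCD1. Adjusted over the list alone, 13 rose. The list's median log2 fold change was 1.13, and it was past the threshold in camera (adjusted p = 2.88e-10) and also with an estimated correlation (adjusted p = 0.0407). CCN2, a matricellular target of TGF-beta, had a value of 1.18 ± 0.33 and was not past the threshold (adjusted p = 0.0885; 0.0166 with the replicate block). Of 9 ligands, receptors and SMADs, 4 rose and 1 fell, and 4 and 2 over the list alone. INHBA, LTBP2 and the inhibitory SMAD7 (1.62, adjusted p = 0.0241) rose and the activin receptor ACVR1B fell (−1.48, adjusted p = 0.00121). That list was not past the threshold in camera at 24 h (adjusted p = 0.0947).

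Some mesenchymal, cytoskeletal and matrix genes rose at 24 h, and most of those tested did not pass the threshold. Of 7 mesenchymal markers, TAGLN, SPARC (1.07, adjusted p = 0.0114) and the N-cadherin gene CDH2 (1.41, adjusted p = 0.0298) rose. Adjusted over the list alone 5 rose, and 5 with the replicate block. The list had an adjusted p of 6.46e-05 (adjusted p = 0.0866 with an estimated correlation). Of 22 actin cytoskeleton genes, 5 rose, including TAGLN2 (0.93), PDLIM7 (1.26) and TPM4 (0.63). Within the list alone 12 rose and 1 fell, and 10 rose and 1 fell with the replicate block. Its adjusted p was 4.61e-05 (adjusted p = 0.155 with an estimated correlation). Of 24 structural matrix genes, 8 rose, including TGFBI, EFEMP1 (1.35), SPARC and the fibrillin gene FBN1 (1.59). Within the list alone 10 rose, 1 fell with the replicate block, and the list had an adjusted p of 0.00438 (adjusted p = 0.522 with an estimated correlation). Among fibroblast markers LUM was at 6.48, 6.115 and 6.82 in untreated, 24 h and 48 h cells and was not past the threshold. COL1A1, below the filter, had means of 1.73 ± 0.39 (SD) in untreated cells, 3.08 ± 0.10 at 24 h and 2.84 ± 0.53 at 48 h. COL3A1 had 1.68 ± 0.28, 1.37 ± 0.10 and 1.44 ± 0.11.

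VIM, the intermediate filament vimentin, was already high in untreated cells at 10.98 and had a value of 0.49 ± 0.16 (adjusted p = 0.153; 0.0269 with the replicate block). FN1 had 0.27 ± 0.16 on its brightest probe set (adjusted p = 0.469), whereas its 2 dim probe sets rose, by 0.86 and 1.55 (adjusted p = 0.0222 and 0.0132 with every probe set tested). ACTA2 (2.47 ± 0.33 untreated, 2.65 ± 0.19 at 24 h, 2.55 ± 0.20 at 48 h), the E-cadherin gene CDH1 (1.28 ± 0.14, 1.10 ± 0.14, 1.15 ± 0.06) and SNAI1 (2.76 ± 0.42, 3.67 ± 0.26, 3.46 ± 0.50) lay below the filter and were not tested. Of 6 EMT transcription factors, SNAI2, a repressor of epithelial genes, rose (2.00 ± 0.23, adjusted p = 0.00121; 1 over the list alone), and ZEB1 was at −0.49 ± 0.47 (adjusted p = 0.673). The list had a median of −0.07, a mean of 0.17 and a camera adjusted p of 0.717, so its median and mean differed in sign.

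Of 11 tested epithelial junction and keratin genes, 3 fell at 24 h: the tight junction gene CLDN1 (−1.70 ± 0.16, adjusted p = 0.000472), EPCAM (−1.27 ± 0.14, adjusted p = 0.00116) and the epithelial transcription factor ELF3 (−1.07, adjusted p = 0.00573). Over the list alone 3 fell and 2 rose, and with the replicate block 2 rose as well. The list was not past the threshold (adjusted p = 0.45), and its median of 0.13 and mean of −0.11 differed in sign. Of 5 proximal tubule genes tested, out of 27 on the array, the kidney transcription factor PAX8 fell (−0.60, adjusted p = 0.0233). Over the list alone 3 fell, and 3 with the replicate block, with a list adjusted p of 0.106. Of 11 tubular injury markers, CLU (−1.27), CD24 (−0.79) and VCAM1 fell, 4 over the list alone, and the list was lower in camera (adjusted p = 0.0143; adjusted p = 0.155 with an estimated correlation).

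Of 8 Notch pathway genes, JAG1 and the target gene HES1 (2.07 ± 0.19, adjusted p = 0.000472) rose, 2 over the list alone as well. The list was not past the threshold (adjusted p = 0.438), with a median of −0.07 and a mean of 0.60. Of 9 Wnt pathway genes, WNT5A (from 2.11 to 4.31, starting at background) and WNT5B (1.95), ligands of non-canonical signalling, rose. Over the list alone 5 rose, and 4 with the replicate block (adjusted p = 0.00449; adjusted p = 0.304 with an estimated correlation). Of 8 BMP pathway genes, FSTL3 (2.19) and the BMP antagonist GREM1 (1.61 ± 0.14, adjusted p = 0.000372) rose and ID2 (−1.45) fell. Over the list alone 3 rose and 1 fell, with a list adjusted p of 0.151. ID1 had a value of 0.55 ± 0.19 (adjusted p = 0.192; 0.0358 with the replicate block). Of 13 matrix proteases and inhibitors, ADAM19 (1.67), MMP1 (2.29) and MMP9 (2.12) rose, 3 over the list alone, and 1 fell with the replicate block, with a list adjusted p of 0.193.

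Among signalling and stress lists at 24 h, IL11 and CXCL5 (1.14) rose and VCAM1 and IL18 (−0.92) fell of 10 inflammatory genes (list adjusted p = 0.717). VEGFC (1.73) and HBEGF (1.17) rose and TGFA (−1.52) fell of 10 growth factor ligands (0.536). JUNB (1.13) and IER3 (0.53) rose and DUSP5 (−1.79) and DUSP6 (−1.93), phosphatases that act on MAP kinases, fell of 13 immediate early genes (0.438). Over these lists alone, 2 rose and 2 fell, 3 rose and 2 fell, and 2 rose and 3 fell. With the replicate block 2 growth factor ligands fell. Of 10 oxidative stress genes the cystine transporter SLC7A11 rose (1.60; list adjusted p = 0.971; 1 rose and 1 fell over the list alone and with the replicate block), and of 11 CDK inhibitors and cytostatic targets CDKN1C fell (−1.34; 0.438; 2 fell over the list alone and with the replicate block).

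No gene passed the threshold at 24 h in limma among 33 cell cycle, 31 oxidative phosphorylation, 15 fatty acid oxidation, 14 cholesterol synthesis, 13 unfolded protein response, 9 antigen presentation or 10 housekeeping genes. List adjusted p-values were 0.95, 0.973, 0.304, 0.425, 0.869, 0.373 and 0.717. The same held for 21 glycolysis and hypoxia genes (0.151; 0.0272 and lower with the replicate block, 0.841 with an estimated correlation), 15 collagen processing genes (0.0947), 6 integrins (0.151) and 5 IGF-binding protein genes (0.694). Adjusted over each list alone, 1 collagen processing gene rose, 1 integrin rose and 1 fell, 1 IGF-binding protein gene rose and 1 fell, and none passed in the others. The members with the smallest p were MCM6 (−0.35), UQCRC1 (0.31), ECH1 (−0.56; adjusted p = 0.0907, 0.0212 with the replicate block), INSIG1 (0.38), DDIT3 (−0.70; 0.0728 and 0.0358), PSMB8 (−0.30), SDHA (0.28), CA12 (−1.71; 0.0789 and 0.00358), P4HA2 (0.80; 0.0549 and 0.00366), ITGA5 (0.90; 0.122 and 0.0268) and IGF1R (1.12; 0.0539 and 0.0118). Another CA12 probe set of similar brightness was lower at 24 h (−1.71) and 48 h (−1.67). It passed at both times (adjusted p = 0.00925 and 0.0101 with every probe set tested). With the replicate block 2 glycolysis and hypoxia genes rose and 4 fell, 2 collagen processing genes rose, 1 integrin rose and 1 fell, 1 IGF-binding protein gene rose and 1 fell, 1 fatty acid oxidation and 1 unfolded protein response gene fell, and 1 gene of the interferon list rose. Median and mean differed in sign for oxidative phosphorylation (−0.02 and 0.02), the unfolded protein response (0.07 and −0.03) and oxidative stress (−0.01 and 0.07), and the inflammatory list had a direction down in camera and up in fry. None of these passed. Too few members of the remaining lists were tested for a set test: 3 interferon-stimulated genes and 3 podocyte markers, of which none passed, 1 fibroblast marker (LUM, which did not pass), 1 distal nephron marker (SCNN1A, above) and 0 endothelial and 0 leukocyte markers.

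In all, 210 genes passed the threshold at 24 h, 115 higher and 95 lower, and 142 of them differed at least 2-fold. With the replicate block the count was 501, with 260 higher and 241 lower, and it included all 210. Without 1 array the count was 105 (untreated replicate 1), 130 (24 h replicate 2) or 116 (24 h replicate 3). It was 182 without 24 h replicate 1, 213 without untreated replicate 2 and 170 without untreated replicate 3. Without a whole replicate it was 34, 129 and 81 for replicates 1, 2 and 3.

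**Figure D1:**
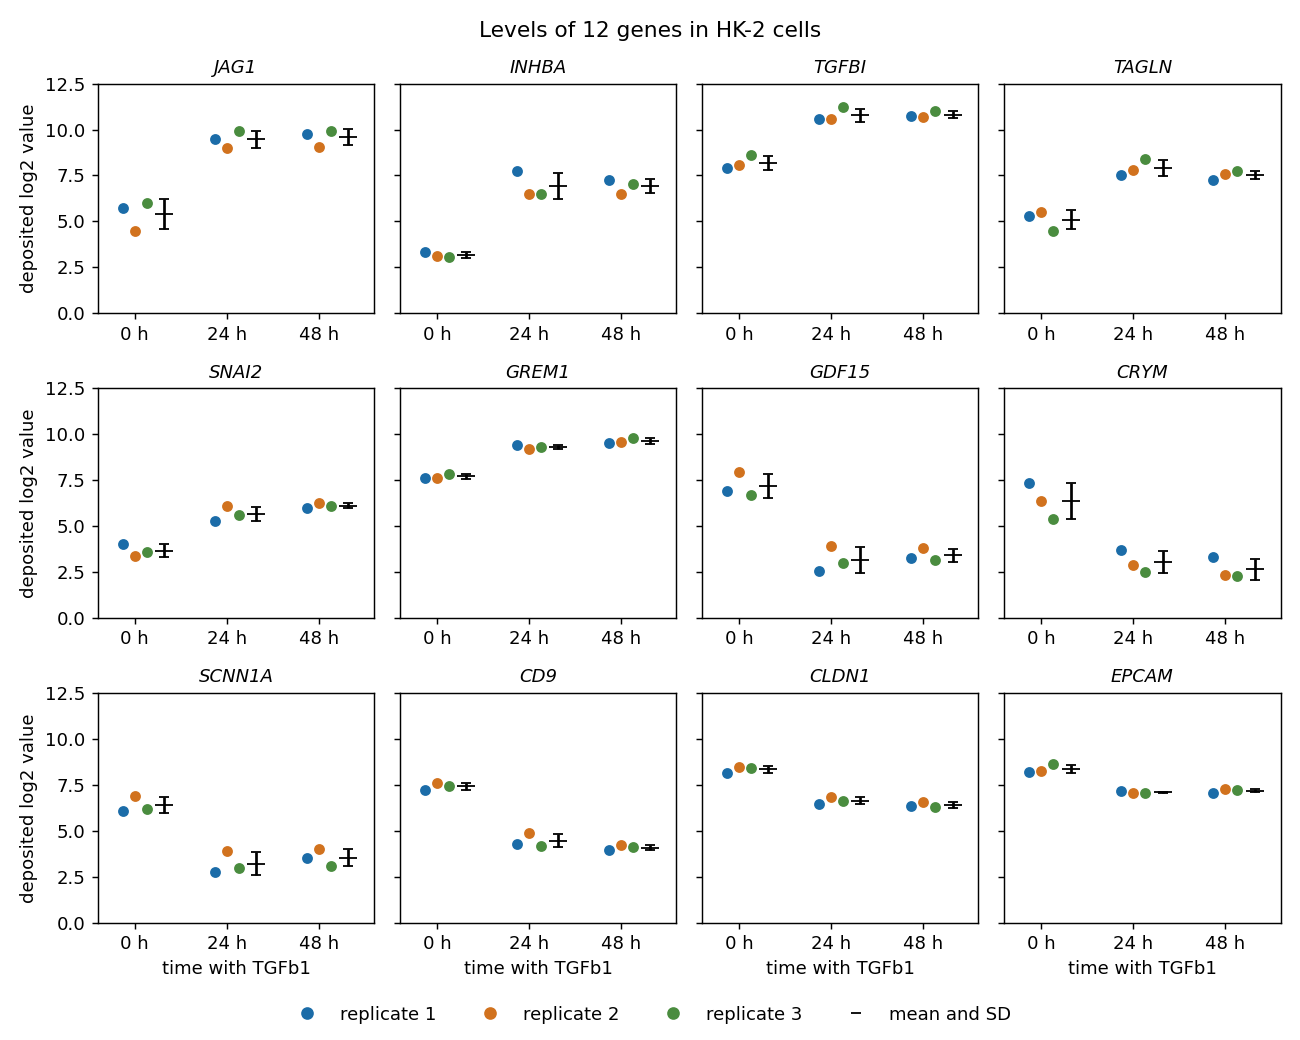
Deposited log2 values of 12 genes (y axis) in untreated cells (0 h) and after 24 h and 48 h of TGFβ1 (x axis), with 1 point per array coloured by replicate number and a bar for the mean and SD of 3 arrays. JAG1 lay at a mean of 5.39 before treatment and 9.46 and 9.59 after it, and GDF15 at 7.19, 3.16 and 3.42.

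After 48 h of TGFβ1, JAG1 was 18.4-fold above untreated cells (4.20, adjusted p = 0.000428) and INHBA 13.5-fold (3.76, adjusted p = 0.000329). MMP1, the interstitial collagenase, had risen 9.32-fold (3.22 ± 0.44, adjusted p = 0.00306), and the cystine transporter SLC7A11 7.83-fold (2.97 ± 0.30, adjusted p = 0.000533). GDF15 had fallen 13.7-fold (−3.77, adjusted p = 0.00075), CRYM 13.4-fold (−3.74 ± 0.50, adjusted p = 0.00262) and CD9 by 3.33 on the log2 scale (adjusted p = 5.42e-05). PDZK1IP1 (−2.46), the fatty acid activating enzyme ACSL1 (−2.37) and DUSP5 (−2.38) joined SCNN1A (7.28-fold), RBM47 (−2.73), MAL (−2.72) and KCNJ16 (−2.71) among the 10 largest decreases.

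The other increases among the 10 largest at 48 h were those of SLCO2A1 (2.77), IL11 (2.70), TGFBI (2.62), TNS1 (2.51), PMEPA1 (2.48) and SNAI2 (2.45). SMAD7 (1.69, adjusted p = 0.0182), CDH2 (2.83-fold, adjusted p = 0.0222), HES1 (2.00), GREM1 (1.94, adjusted p = 0.000142) and ID1 (0.97, adjusted p = 0.0214) also rose. CCN2 (0.60, adjusted p = 0.513), VIM (0.47, adjusted p = 0.185; 0.0341 with the replicate block), FN1 (0.53, adjusted p = 0.109; 0.0421 with the replicate block) and ZEB1 (−0.49, adjusted p = 0.78) were not past the threshold. The 2 dim FN1 probe sets rose, from 3.21 to 5.04 and from 3.32 to 6.32 (adjusted p = 0.00043 for both with every probe set tested).

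Of 16 TGF-beta early target genes, 6 rose and 0 fell at 48 h, including PMEPA1, TGFBI, LTBP2 (1.01) and LMCD1 (2.18). Over the list alone 11 rose, and with the replicate block 11 rose and 1 fell (adjusted p = 1.11e-09; adjusted p = 0.0474 with an estimated correlation). Of 9 ligands, receptors and SMADs, 3 rose and ACVR1B (−1.39) fell, 4 and 1 over the list alone and 5 and 1 with the replicate block (adjusted p = 0.0097; adjusted p = 0.197 with an estimated correlation). Of 7 mesenchymal markers, TAGLN (2.44), SPARC (1.29) and CDH2 rose, 6 over the list alone and 6 with the replicate block (adjusted p = 4.55e-05; adjusted p = 0.0737 with an estimated correlation). Of 24 matrix genes, 6 rose, including TGFBI, EFEMP1 (2.12), FBN1 (2.34) and SPARC, and 9 over the list alone (adjusted p = 0.000428; adjusted p = 0.338 with an estimated correlation). Of 22 actin cytoskeleton genes, 5 rose, including TAGLN, PDLIM7 (1.08), TPM4 (0.65) and TPM1 (0.51), 9 over the list alone and 11 with the replicate block (adjusted p = 0.00127; adjusted p = 0.274 with an estimated correlation). WNT5A (2.39) and WNT5B (1.47) rose of 9 Wnt pathway genes and 3 over the list alone (adjusted p = 0.00348; adjusted p = 0.286 with an estimated correlation).

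CLDN1 (−1.94), EPCAM (−1.17) and ELF3 (−1.08) fell at 48 h, while the desmosome gene DSP rose (1.73, adjusted p = 0.0108), so that of 11 epithelial genes 1 rose and 3 fell (3 and 3 over the list alone, 2 and 3 with the replicate block; list adjusted p = 0.149). Of 9 antigen presentation genes the immunoproteasome subunit PSMB8 fell (−0.69; 1 over the list alone), and the list was lower (adjusted p = 0.0124; adjusted p = 0.286 with an estimated correlation). Of 11 tubular injury markers CLU fell (−1.21), 1 rose and 3 fell over the list alone, 1 rose and 2 fell with the replicate block, and the list was lower (adjusted p = 0.0214; adjusted p = 0.201 with an estimated correlation). VCAM1, at −1.92, was not past the threshold at this time (adjusted p = 0.0524; 0.00135 with the replicate block). PAX8 fell (−0.81), with 3 of 5 proximal tubule genes lower and 1 higher over the list alone and with the replicate block (list adjusted p = 0.0978). Of 10 inflammatory genes, IL11 and CXCL5 (1.15) rose and ICAM1 (−0.70) and IL6 (−0.94) fell, 2 and 5 over the list alone and with the replicate block. The list's adjusted p was 0.0978, 0.0451 and lower with the replicate block, and 0.42 with an estimated correlation.

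FOSL1 (−1.09), DUSP5 and DUSP6 (−1.83) fell among 13 immediate early genes (list adjusted p = 0.0735; 1 rose and 3 fell over the list alone and with the replicate block). Single genes passed in 6 further lists at 48 h: VEGFC (1.99) rose of 10 growth factor ligands (0.544; over the list alone 3 rose and 2 fell, and 3 rose and 1 fell with the replicate block), IGF1R (1.47) of 5 IGF-binding protein genes (0.862), P4HA2 (0.86) of 15 collagen processing genes (0.0978; 2 with the replicate block) and SLC7A11 of 10 oxidative stress genes (0.489). IGF1R encodes a receptor and not a binding protein. DDIT3 (−0.80) fell of 13 unfolded protein response genes (0.63). SNAI2 rose of 6 EMT transcription factors (0.371). ADAM19 (1.43) rose with MMP1 of 13 matrix proteases (0.628), and JAG1 and HES1 of 8 Notch genes (0.187). GREM1, FSTL3 (1.53) and ID1 rose while ID2 (−1.08) fell of 8 BMP pathway genes (0.127). No gene passed in limma among the cell cycle (0.0978), CDK inhibitor (0.371), fatty acid oxidation (0.149), oxidative phosphorylation (0.284), cholesterol synthesis (0.371), glycolysis and hypoxia (0.203), integrin (0.102) and housekeeping (0.633) lists. The integrin gene ITGB3 was at 0.80 (adjusted p = 0.0582; 0.019 with the replicate block), and 4 integrin genes rose and 1 fell over the list alone and with the replicate block. The members with the smallest p in the other lists without a call were KIF11 (0.57), CDKN1A (−1.04; adjusted p = 0.0659, 0.00455 with the replicate block), ECH1 (−0.59; 0.0772 and 0.0191), NDUFA1 (−0.22), SQLE (0.28), PFKL (−0.62; 0.124 and 0.00999) and GUSB (−0.26). With the replicate block 2 CDK inhibitor genes fell, also over the list alone, 1 cell cycle gene rose, 1 glycolysis and hypoxia gene rose and 3 fell, and 1 gene each fell of the fatty acid oxidation, oxidative stress and matrix protease lists. Median and mean differed in sign for matrix proteases (−0.03 and 0.19), Notch (−0.03 and 0.70), IGF-binding proteins (−0.12 and 0.16) and the unfolded protein response (0.09 and −0.04), none of which passed.

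At 48 h 194 genes passed the threshold, 99 higher and 95 lower, and 125 differed at least 2-fold. With the replicate block the count was 438, with 228 higher and 210 lower, and it included all 194. Without 1 array the count was 119 (untreated replicate 1), 112 (48 h replicate 1) or 111 (48 h replicate 3). It was 134 without 48 h replicate 2, 153 without untreated replicate 2 and 206 without untreated replicate 3. Without a whole replicate it was 33, 112 and 79 for replicates 1, 2 and 3.

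**Figure D2:**
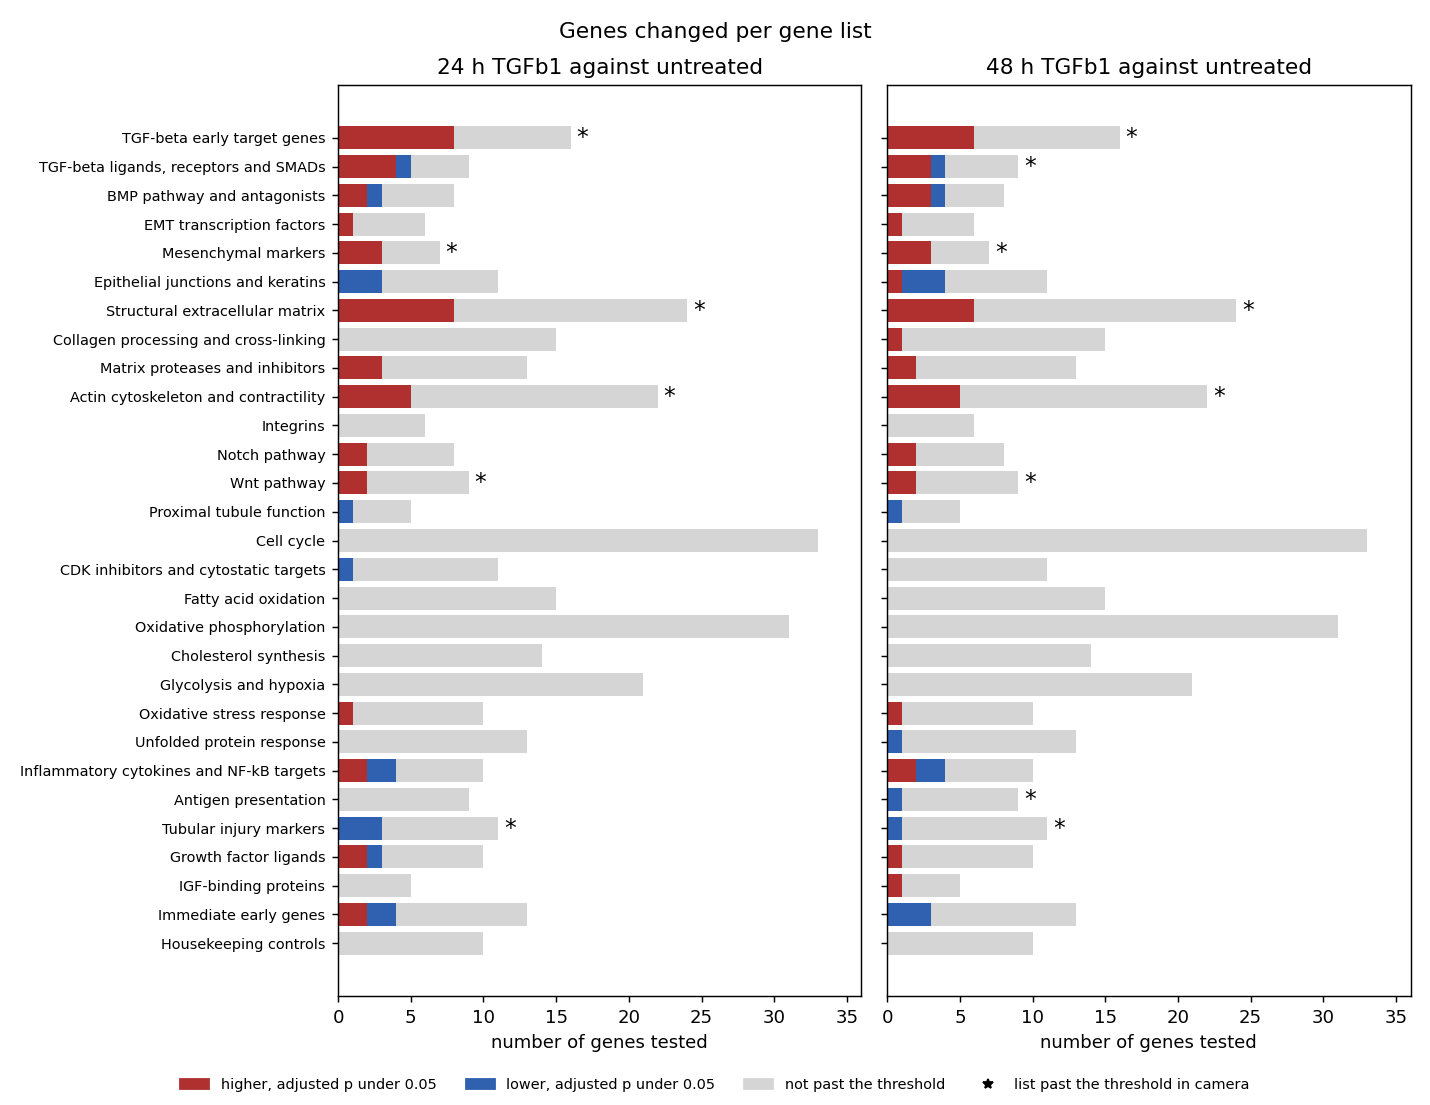
Number of tested genes (x axis) in each of 29 gene lists (y axis) that were higher (red), lower (blue) or not past the adjusted p threshold of 0.05 (grey) after 24 h (left) and 48 h (right) of TGFβ1, with an asterisk where the list passed the threshold in camera at the preset correlation. The list of TGF-beta early target genes had 8 genes higher at 24 h and 6 at 48 h of 16, and 0 of 33 cell cycle genes passed at either time.

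Between 24 h and 48 h of TGFβ1 no gene passed the threshold in limma. The smallest adjusted p-values, both 0.353, were those of FXYD2, a regulator of the renal sodium pump, at −1.07 ± 0.165, and of the transcription elongation factor CTR9 at 0.94. SLC7A11 (1.36 ± 0.30), MMP9 (−1.72 ± 0.41), the tubular aminopeptidase ENPEP (1.35 ± 0.33) and IL6 (−0.81 ± 0.18) had large values with an unadjusted p under 0.05 and did not pass either. These 6 genes were chosen after their values were seen. Of the fixed genes, SNAI2 (0.45), ID1 (0.42), GREM1 (0.33), FN1 (0.26) and CCN2 (−0.58) had an adjusted p of 0.781, and JAG1 (0.12 ± 0.41), CDH2 (0.09 ± 0.30), SMAD7 (0.08 ± 0.33), HES1 (−0.07 ± 0.19), VIM (−0.02 ± 0.16) and ZEB1 (0.00 ± 0.47) lay within their SE of 0. At an unadjusted p under 0.05 there were 219 genes, 5.01% of those tested, and with the replicate block 709, or 16.2%, more than the 5% of chance, of which 0 passed after adjustment (smallest adjusted p = 0.0751). Adjusted over a list alone, 1 gene passed in each of 5 lists, MMP9 of the protease, SLC7A11 of the oxidative stress and IL6 of the inflammatory list among them. None of the 29 lists passed in camera (smallest adjusted p = 0.0567, matrix proteases, and 0.0722, cell cycle; 0 also with an estimated correlation, with fry and with the block).

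The changes at both times were compared across genes. Of the genes called, 79 were higher at both times, 64 lower at both and 0 opposite, 143 in all (316 in the same direction with the replicate block). A further 67 were called at 24 h and not at 48 h and 51 at 48 h and not at 24 h, although no such gene passed the test between the times. JAG1, INHBA and TGFBI were among those higher, and GDF15, CD9 and EPCAM among those lower. Independent lists of these sizes would share 2.61 genes higher and 2.07 lower, and simulated groups with no effect against the same controls shared 0. The first leaves out the shared untreated arrays and the second the effects, and the 3 untreated arrays are too few to split, so part of the excess of shared calls may come from the shared controls. Across the 4368 genes, which are not independent replicates, the log2 fold changes at 24 h and 48 h correlated with r = 0.825 and rho = 0.618. Simulated groups with no effect gave a mean r of 0.501, since both comparisons use the same untreated arrays, and rho was not simulated. The sign was the same at both times for 70.4% of genes, against a mean of 66.7% simulated. The covariance was 0.167 against 0.0315 simulated, a difference of 0.135. The simulated arrays were independent of each other, unlike the real arrays of 1 run. An F test over the 3 groups called 180 genes, and 491 with the replicate block.

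**Figure D3:**
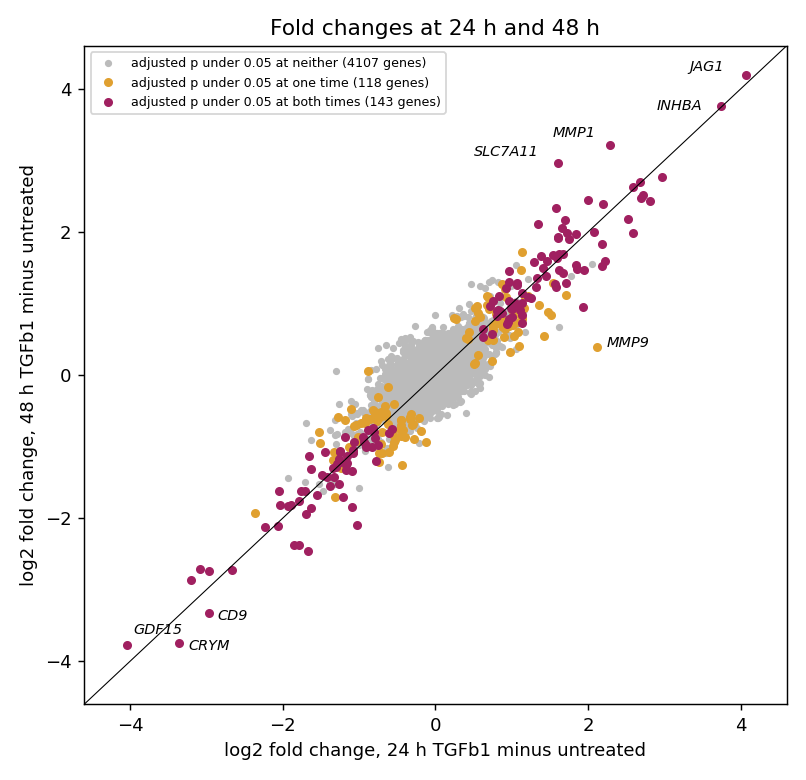
Log2 fold change against untreated cells at 24 h (x axis) and 48 h (y axis) of TGFβ1, with 1 point per gene of 4368 tested, coloured by whether the adjusted p was under 0.05 at neither time, at 1 time or at both (143 genes), and a line where both are equal. JAG1 lay at 4.07 and 4.20, GDF15 at −4.04 and −3.77, and MMP9 at 2.12 and 0.39.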

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

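The counts of probe sets below were taken outside the comparisons of genes. Of 3151 probe sets with several listed genes or none, 763 passed the filter, and 21 of them differed between 24 h of TGFβ1 and untreated cells, 11 higher and 10 lower (limma, adjusted p under 0.05). At 48 h 23 differed, 9 higher and 14 lower, and between the 2 times 0 did. They drew attention because they are signal in probe sets that no comparison of genes used, and they are not named here because no single gene could be given to them.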

How the results depend on the processing

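All alternatives were chosen before the data were examined. Among 160 results of named genes, 113 were past the threshold. Of their 2105 values under alternatives 0 changed sign, 1787 stayed past the threshold and 318 did not, among them 71 without replicate 1, 27 without replicate 2 and 47 without replicate 3, where fewer arrays were fitted. Of the values not past it, 62 became so. The replicate block, the filter, the variance model and the groups in the fit leave the log2 fold change of a gene unchanged. Genes named for groups without overlap cannot change sign when arrays are left out. The 0 sign changes are therefore only in part a test of direction. Counts of 210 genes at 24 h and 194 at 48 h became 501 and 438 with the replicate block, 408 and 514 with array weights, and 84 and 89 at an adjusted p under 0.01; with only the compared groups in the fit 24 h gave 124, and with a log2 fold change of at least 1 the 48 h count was 125. With 1 array or 1 replicate left out they ranged from 34 to 213 and from 33 to 206. The F test gave 491 genes with the replicate block and 26 to 105 without 1 replicate, and 316 genes were called at both times with the block. Between 24 h and 48 h 0 genes passed under any alternative. Lists past the threshold in camera (6 and 8) fell to 1 and 1 with an estimated correlation. With fry 12 and 13 passed, but fry does not compare a list with the other genes, so these counts answer another question. Between 24 h and 48 h 2 lists passed in camera with no filter. With the replicate block 16 uncalled results of named genes became past the threshold, and 0 called ones were lost. At 48 h the uncalled value of MMP9 was 0 with values below 4 raised to 4, since every array of both groups lay under 4. Several uncalled values between 24 h and 48 h changed sign: VIM went to 0.023 with quantile normalization, ZEB1 to 0.17 with array weights and HES1 to 0.024 on another probe set. With 1 array or replicate left out, these uncalled differences ranged from −0.041 to 0.195 for SMAD7, −0.111 to 0.334 for CDH2, −0.127 to 0.090 for VIM, −0.466 to 0.489 for ZEB1, −0.101 to 0.387 for JAG1 and −0.231 to 0.042 for HES1. The cause was not tested. Genes near the array median of 2.2 lie at background, which limits what can be said of ACTA2, CDH1 and COL1A1.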

Other observations

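The tests of splits were planned; the tests on fibroblast transcripts, time in culture, power, the ratio of the times, ERK output and immediate early genes were chosen or changed after related results were seen. Few other kidney cell markers passed the filter: 3 of 10 podocyte, 1 of 15 distal nephron and 1 of 16 fibroblast markers on the array. Of 27 proximal tubule genes on the array 5 passed it. The distal nephron marker was SCNN1A, which fell at both times. The podocyte markers PTPRO (10.5, 10.1 and 10.2 in untreated, 24 h and 48 h cells), CD2AP (7.38, 7.08 and 7.40) and NES (4.14, 4.45 and 4.09) were measured and were not past the threshold, and the fibroblast marker LUM, a matrix proteoglycan, was at 6.48, 6.115 and 6.82, not past it either. JAG1 is read by 3 probe sets that rose at 24 h, by 4.07, 3.90 and 4.82, and by 1 at background, at 1.95, 1.74 and 2.03. FN1 is read by 4 bright probe sets near 11, none past the threshold, and by 2 dim ones that rose, to 6.32 and 5.04 at 48 h.

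Some matrix, cytoskeletal and mesenchymal genes rose at both times, 8 of 24, 5 of 22 and 3 of 7 at 24 h and 6, 5 and 3 at 48 h, while none of these 3 lists passed in camera with an estimated correlation (adjusted p = 0.0737 to 0.522). That correlation was estimated without the replicate block and includes shifts between runs. It therefore cannot decide whether the lists would pass with the runs accounted for. Fibroblasts among the treated cells would bring abundant fibroblast transcripts. The highest treated mean among COL1A1, COL1A2, COL3A1, DCN, PDGFRB and THY1 was 3.08 (COL1A1, from 1.73 in untreated cells), below the filter of 4. COL1A2, COL3A1, PDGFRB and THY1 had no higher mean in treated than in untreated cells, while COL1A1 and DCN did. None of these transcripts was abundant in treated cells. The bound was the filter, not a level known for a given share of fibroblasts, and it was set after related values were seen. It therefore cannot tell what share of fibroblasts would go unseen. COL1A1 was added to the set after its value was seen. LUM, outside the set, lay above the filter in every group. It was at −0.37 at 24 h and 0.33 at 48 h against untreated cells, not past the threshold, which decides nothing. With quantile normalization of the deposited values all 3 lists stayed past the threshold at both times at the preset correlation, and 214 and 209 genes passed in all. GCRMA had already normalized between arrays, and this step moved the median log2 fold change by only −0.009 at 24 h and −0.019 at 48 h. It therefore cannot decide whether a shift of scale between arrays contributed. Time in culture rather than TGFβ1 stays open and cannot be told apart from treatment, since 0 untreated arrays were at 24 h or 48 h.

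No gene passed the threshold between 24 h and 48 h, though with the replicate block 709 genes, 16.2%, had an unadjusted p under 0.05 (smallest adjusted p = 0.0751), so differences between the times are not excluded. A candidate explanation is that the response had reached its later size by 24 h: over the 180 genes past the F test the median ratio of the 48 h to the 24 h log2 fold change was 0.990, with quartiles of 0.848 and 1.20, though 19 genes had a ratio above 1.5 and 10 below its inverse. Simulated data with a ratio of 1.5 and the same untreated arrays in both comparisons gave a mean of 1.497, and with a ratio of 1 a mean of 1.0004. In these simulations the shared arrays did not pull the median ratio to 1. They took the observed 24 h changes of the 180 genes as true. Those changes carry the selection of the genes and the error of the shared arrays, so a pull in the real data is not excluded. Too few arrays stay open as the other explanation, since 67.7% of genes simulated with a log2 change of 1 between the times were called, fewer than the 90% set as the bound. That simulation drew the arrays independently, without the correlation between arrays of 1 run, and used no replicate block. The power of the fit with the block was not simulated. The simulation also changed 200 genes per run, and the adjustment is stricter where fewer genes change. The share called may therefore be lower in the real comparison, where none passed.

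DUSP5 and DUSP6, which are induced by ERK signalling, fell at both times. Lower output of the ERK pathway may account for this, but 10 other ERK feedback and output genes had a median of 0.05 at 48 h with members both ways (camera adjusted p = 0.869; FOSL1 fell), which decides nothing. A general fall of immediate early transcripts was not seen in 8 others either (camera adjusted p = 0.869), and it also stays open. The reading of the ERK test was changed after its value was seen, because the median exceeded 0 by less than its spread, and both p-values were adjusted over the 2 lists after they were seen, which moved no reading.

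Other splits of the arrays were fitted. For 24 h against untreated 1 of 10 splits, the real one, gave as many as 210 genes (highest other 5); for 48 h 1 of 10 gave 194 (highest other 0); between 24 h and 48 h all 10 of 10 gave 0. These splits are too few for a share under 0.05. For the F test 2 of 100 drawn splits gave at least the 180 genes of the real one, a share under 0.05. Most drawn splits put arrays of 1 replicate number in the same group. Arrays of 1 number correlated with each other, so this share cannot decide against chance. The other, with 213, kept the 3 untreated arrays together, and splits that part them gave at most 19. Of the 13 drawn splits that part every replicate number over the groups, 1 gave as many, the real one (highest other 150), and 13 are too few for a share under 0.05.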
